A study of Mus musculus with 14 samples.

How the data were processed

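The series holds single-cell RNA-seq of lineage-negative, Tom-positive mouse cells (the labels give the reporter only as Tom). Cells were sorted into plates of 96 wells, and libraries were made with a Smart-seq2 variant that reads the 3′ end of each transcript, per the labels' protocols. The 14 plates came from 5 mice. Mouse m4539 was sampled at day 3 (2 plates), mouse m4533 at day 10 (3 plates), and mice m4528 (4 plates), m605 (2 plates) and m606 (2 plates) at day 17. A further day 17 plate held cells of mice m605 and m606 together. Days and mice were taken from the sample titles, which do not say from which event the days were counted.

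The authors deposited 2 tables of raw counts per gene and barcode, without normalization. The first table holds mice m4539, m4533 and m4528, and the second table holds mice m605 and m606. Column names tie each barcode to its plate. The genome build was GRCm38 per the submitters' processing notes, and the aligner and counting tool are not given in the sources used here. The counts were whole numbers. Among the kept cells of the first table, 55.5% of the values above 0 lay between 1 and 5 but held 1.72% of the counts, and the median of the larger values was 70 counts. In the second table these figures were 49.3%, 2.77% and 28 counts. Whether molecular identifiers were used is not given in the sources used here, so each count was treated as a read, and intervals and floors cover counting error only. Genes were matched between tables by symbol, which both tables print in capitals. The first table lists 22971 genes, the second table lists 34486, of which 2809 had no counts, and 22842 genes were in both and entered every analysis. How reads were split between near-identical copies is not known, so values of Hspa1a (copy Hspa1b), Ly6c2 (copy Ly6c1), Mt-Rnr2 (nuclear copies) and ribosomal protein genes are uncertain. No gene of the tables carried the name of the reporter.

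The tables hold 9357 barcodes, many more than the plates have wells. A planned filter of at least 500 detected genes alone kept 1672 barcodes, above the number of wells. A minimum of 10000 counts per cell was therefore added after the totals had been seen. Both filters together kept 1010 cells, 585 in the first table and 425 in the second table. In the first table the left-out barcodes reached 8372 counts and the kept cells began at 20121, while in the second table these totals were 9704 and 10155. Of the counts, 96.8% to 99.7% per plate lay in kept cells. No doublet caller was run, because wells were filled by sorting. As an alternative, 2 cells were left out whose log10 totals lay more than 3 median absolute deviations (scaled to the SD of a normal distribution) above the median of their table. On the scale of counts, unscaled, the same rule left out 147 cells, and this version was added after the data had been seen. All 91 pairs of plates were compared over genes with at least 100 counts, and the lowest chi-square per gene was 28.8, so no plate was a copy of another.

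Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 20 principal components, 15 neighbours and a Leiden resolution of 1 gave 11 clusters. The 600 shared genes of the S phase, G2M phase, ribosomal protein, mitochondrial respiration, mitochondrial genome, glycolysis, cholesterol synthesis, interferon response, and immediate early and stress lists were kept out of clustering, so that they could be compared between classes. Genes outside these lists that vary together with them could still enter clustering, so the lists are not independent of the classes. The HSC-like cluster 5 has 6 immediate early and stress genes among its 10 leading genes. Clusters were named from 13 marker lists fixed before the data were examined (HSC, multipotent progenitor, megakaryocyte, erythroid, neutrophil, monocyte, dendritic cell, lymphoid, basophil or mast cell, eosinophil, macrophage, stromal or endothelial, and mature B or plasma cell). A name needed at least 3 markers that exceeded the other cells by 1.5 times and that were found at more than 10 counts in at least 10% of the cluster's cells, with a lead of 2 markers over the next class and no other class ahead among the 10 leading genes of the cluster. These thresholds were set after the data had been seen, and the clusters they left without a name are reported by number.

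Counts were summed over the kept cells of each mouse, and over the cells of a class where the mouse had at least 10 of them. The mouse was the replicate. The change with day was tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr) in R 4.3.3 as a slope over day with the table as a term, and is printed as log2 change per 14 days. With 5 mice this left 2 residual degrees of freedom. The second table holds day 17 only, so with that term the fitted slope is drawn from the 3 mice of the first table, and the spread comes from the departure of those 3 mice from a line and from the difference between mice m605 and m606. Day 3 and day 10 have 1 mouse each, so they are compared as values only. Classes were compared with HSC-like cells by the same test with the mouse as a block, because both sums come from the same animal. Adjusted p-values are Benjamini-Hochberg at a threshold of 0.05, over all genes tested unless said otherwise. Gene lists of at least 5 tested genes were tested with camera (limma 3.58.1, preset correlation of 0.01, and again with an estimated correlation) and fry. Shares of cells have exact Clopper-Pearson 95% intervals, and a share of 0 is given with the upper end of its interval. Day 17 mice were set against the 2 earlier mice by a two-sided exact permutation test over 10 splits, whose smallest p is 0.1. Levels in CPM (counts relative to the total of the library) in the accounts of change with day and of class contrasts are scaled by TMM. Values for plates, barcodes left out and background comparisons are plain CPM.

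The genes named were fixed by a rule set before the data were examined. It took up to 12 higher and 12 lower genes past the threshold with a mean of at least 10 CPM, the 3 members of each list with the lowest p, past the threshold or not, and Pdzk1ip1. Genes outside the rule are marked as chosen afterwards. Gene positions are from the RefSeq annotation of GRCm38. The fits were tested on simulated counts with 200 changed genes, 100 at 4-fold and 100 at 16-fold. At a 4-fold change the day fit over all cells recovered 16%, that over HSC-like cells 1%, the megakaryocyte-like contrast 21% and the erythroid-like contrast 19%. At 16-fold the shares were 75%, 25%, 79% and 73%. False calls were 7, 3, 2 and 5.

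The alternatives tried were RLE size factors, no filter on low counts, DESeq2 1.42.0, no table term, day as a factor, no mouse block, cells thinned to 9000 counts, at least 1000 genes per cell, each mouse or plate left out in turn, the mixed plate as a further unit, other resolutions, separate clustering of the tables, and naming each cell by its highest marker score. Added after the data had been seen were the planned filter of 500 genes alone, a mean of at least 10 CPM per gene, leaving out the highest-count cells on the scale of counts, and leaving out the HSC-like cluster led by immediate early genes. In the sum of all cells the median fitted change of all genes with day was 0.03 under TMM and −0.09 under RLE, and in the contrast of erythroid-like with HSC-like cells it was 0.22 and 0.10. These shifts of over 0.1 on the log2 scale apply to the changes of these 2 fits, and in the other 4 fits the shift was at most 0.08. The plate of mice m605 and m606 together entered no mouse sum, because its cells carry no mouse name.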

Results

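The series followed endogenous blood stem cells by inducible lineage tracing, in which a switched-on fluorescent reporter (Tom) passes to the progeny of the stem cells in which it was turned on. Bone marrow stem cells (hematopoietic stem cells, HSC) sit at the top of the blood lineages, and the lineage-negative gate removes most mature blood cells. Single reporter-positive cells were sequenced at days 3, 10 and 17. After filtering, 190 cells of mouse m4539 (day 3), 107 of mouse m4533 (day 10), and 288, 143 and 189 of mice m4528, m605 and m606 (day 17) remained, with 28934071, 40041487, 64257177, 25482791 and 30315939 counts. The median cell held 127190, 286917, 163430, 124918 and 118001 counts in the same order of mice. A plate of mice m605 and m606 together added 93 cells and 15121279 counts. Day 3 and day 10 had 1 mouse each and so no replicate error. Mouse m4528 differed from the other mice in sex-linked genes. It had 0.156 CPM of Xist, the transcript of the inactive X chromosome, and 131 CPM of the Y-linked gene Eif2s3y, while the other 4 mice had 181 to 1242 CPM of Xist and at most 0.20 CPM of Eif2s3y.

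The first comparison asked which cell types the reporter-positive cells held at each day. At day 3 most cells were HSC-like, and at day 17 the cells were spread over stem, megakaryocyte, erythroid and myeloid classes. HSC-like cells, in 3 clusters with 13, 10 and 4 of the 15 HSC markers, made up 81.6% of the cells at day 3 (exact 95% interval 75.3 to 86.8), 52.3% at day 10 (42.5 to 62.1) and 15.6% ± 4.02 (SD, n = 3 mice) at day 17. Megakaryocyte-like cells, the platelet lineage, were 6.84% (3.69 to 11.4) at day 3, 27.1% (19.0 to 36.6) at day 10 and 18.9% ± 3.61 at day 17. Erythroid-like cells were 1.05%, 2.80% and 15.5% ± 11.1, with 3.82%, 25.9% and 16.9% in mice m4528, m605 and m606. Monocyte-like cells were 0 of 190 at day 3 (exact 95% interval up to 1.92%), 2.80% at day 10 and 18.1% ± 2.16 at day 17. Neutrophil-like cells were 0 of 190 at day 3, 0.935% at day 10 and 5.42% on average at day 17 (6.25%, 6.29% and 3.70% in mice m4528, m605 and m606). Basophil or mast cell-like cells were 0 of 190, 0 of 107 (exact 95% interval up to 3.39%) and 10.5% ± 3.63. The last class had 9 of 11 of its own markers raised, but also 5 of 10 multipotent progenitor and 5 of 19 erythroid markers. With the tables clustered separately, 9 cells of the second table had this name. A cluster of 61 of its cells, led by Clec4d, Gm15915 and Trib2, had none.

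**Figure D1:**
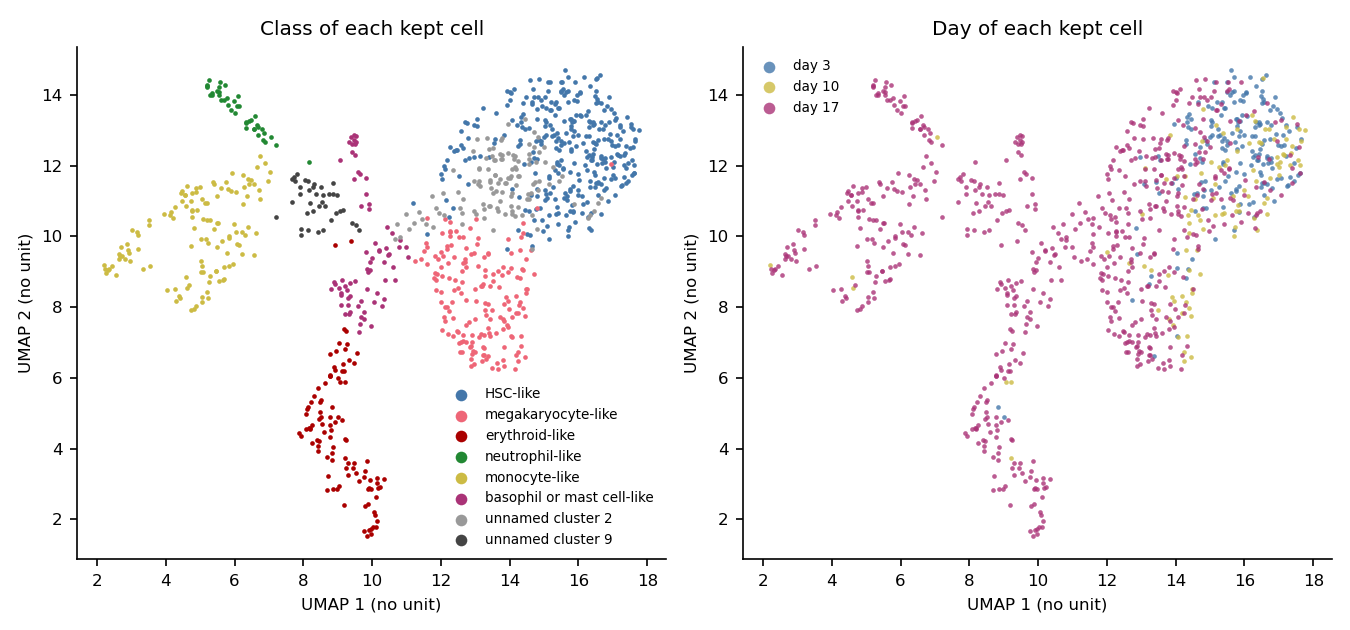
UMAP of the 1010 kept cells (both axes without unit), each point 1 cell, coloured by class on the left and by day on the right. Day 3 and day 10 cells lie mostly in the HSC-like and megakaryocyte-like parts, and the erythroid-like, monocyte-like, neutrophil-like and basophil or mast cell-like arms hold nearly only day 17 cells.

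**Figure D2:**
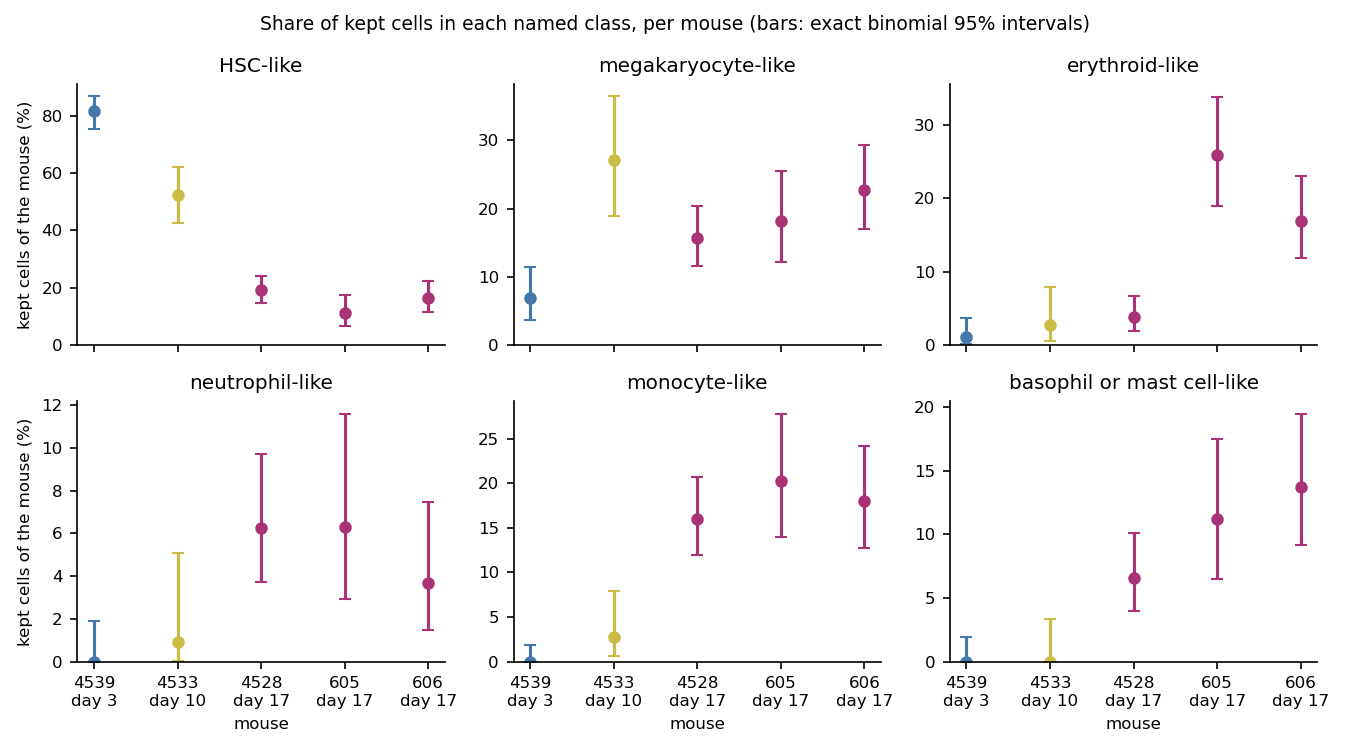
Percent of the kept cells of each mouse in each named class, with exact binomial 95% intervals as bars, 1 point per mouse and a vertical scale of its own in each panel. The HSC-like share was 81.6% in the day 3 mouse, 52.3% in the day 10 mouse and 11.2% to 19.1% in the 3 day 17 mice.

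In the two-sided exact permutation test of the 3 day 17 mice against the 2 earlier mice, HSC-like, neutrophil-like, monocyte-like and basophil or mast cell-like shares reached p = 0.1, the smallest the 10 splits allow (Benjamini-Hochberg adjusted p = 0.16 over 8 classes). The erythroid-like share had an exact p of 0.2 (adjusted 0.267) and the megakaryocyte-like share 0.9 (adjusted 1). A pair of clusters stayed without a name. Cluster 2, with Il2rg, Cd27 and Hlf among its leading genes and 4 HSC and 4 multipotent progenitor markers, held 10.5% of the day 3 cells, 15 of 107 day 10 cells and 27.1%, 2.10% and 3.70% in mice m4528, m605 and m606. Cluster 9, with 8 multipotent progenitor and 7 neutrophil markers, was found at day 17 only (5.07% ± 0.425). Shares moved by over 1.5 times with the filters, the clustering or the naming. The megakaryocyte-like share of cells at day 10 was 17.8% by marker score, 10.3% with the 147 highest-count cells left out and 3.50% at 500 genes alone, where the megakaryocyte-like share of cells at day 3 was 4.95%. The HSC-like share of cells at day 10 was 29.0% by marker score, and the HSC-like share of cells at day 17 ran from 8.70% to 26.9% over Leiden resolutions of 2 and 0.5. The monocyte-like share of cells at day 17 was 6.83% by marker score. The neutrophil-like share of cells at day 17 was 14.8% at 500 genes alone, and the basophil or mast cell-like share of cells at day 17 was 0 at a resolution of 0.5. The sort gate and the count minimum can set any of these shares.

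The next comparison asked which genes changed with day in all kept cells of a mouse, a measure that follows the mix of cells as well as each cell. Fitted changes were negative for HSC genes and mostly positive for genes of myeloid, basophil and proliferating cells, but no gene passed over all genes and no list was called with an estimated correlation. Mllt3, a chromatin reader that maintains stem cells (chromosome 4, 87769925 to 88033407), had 902 CPM at day 3, 454 at day 10 and 152 ± 37.0 (SD, n = 3) at day 17. Pdzk1ip1 (chromosome 4, 115088708 to 115093894), a marker of stem cells, had 813, 272 and 200 ± 24.0 CPM, and the interferon-inducible membrane gene Ifitm1 had 1269, 280 and 273 ± 29.3 CPM. Mpo, the myeloperoxidase of neutrophil granules (chromosome 11, 87793784 to 87804412), had 41.8 CPM at day 3, 175 at day 10 and 2911 ± 330 at day 17, a 69.6-fold difference between days 3 and 17.

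All 15 HSC list genes had negative fitted changes with a median of −1.81 on the log2 scale. Mllt3 (−2.22, SE 0.31, adjusted p = 0.271 over all genes and 0.0131 adjusted over the list alone by edgeR's quasi-likelihood test) and Pdzk1ip1 (−1.98, SE 0.42, 0.0440 adjusted over the list alone) were the members past the threshold adjusted over the list alone. Of 10 multipotent progenitor genes, 3 were higher adjusted over the list alone, namely Plac8 with 78.5 CPM at day 3 against 2687 ± 516 at day 17, Cdk6, a kinase of cell cycle entry, with 102 against 365 ± 27.2, and Cd48, a surface protein absent from the classical stem cell gate, with 3.81 against 185 ± 47.6. The list's median change was 0.79. Erythroid genes did not pass with the list adjusted alone. Klf1, the master factor of red cells, had 70.1, 141 and 420 ± 153 CPM (0.0577 adjusted over the list alone), and Car1, a carbonic anhydrase of red cells, 186, 362 and 1410 ± 802 CPM (0.0731). The 14 megakaryocyte genes tested split into 7 with positive and 7 with negative changes.

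Of 16 neutrophil genes, 14 were higher adjusted over the list alone. Ms4a3, a marker of granulocyte and monocyte progenitors, had 12.4 CPM at day 3, 69.8 at day 10 and 833 ± 101 at day 17, and Lcn2, an iron-sequestering granule protein, had 0.0318 (1 count), 3.39 and 37.3 ± 25.7 CPM. Of 13 monocyte genes, 11 were higher adjusted over the list alone, among them Ly6c2 (38.7, 155 and 1276 ± 110 CPM), a surface marker of classical monocytes whose reads may be shared with its copy, Ly86 (7.85, 51.0 and 187 ± 28.6 CPM) and Ms4a6c (46.1, 111 and 405 ± 56.7 CPM). Of 10 basophil or mast cell genes, 8 were higher adjusted over the list alone. Hdc, the enzyme that makes histamine (chromosome 2, 126593659 to 126624025), had no counts at day 3, 0.237 CPM at day 10 and 72.6 ± 28.3 at day 17, at least 762-fold higher than a floor of 3 counts in the day 3 mouse. The mast cell protease Cpa3 had 0.350, 5.74 and 207 ± 52.6 CPM, and the basophil protease Mcpt8 0.0953 (3 counts), 7.06 and 261 ± 148 CPM.

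All 35 S phase genes had positive changes (median 1.42), and 23 passed adjusted over the list alone. Rrm2, the regulated subunit of the enzyme that makes deoxynucleotides, had 73.9, 217 and 367 ± 48.7 CPM, the replication helicase subunit Mcm5 101, 147 and 304 ± 31.8 CPM, and the replication factor Cdc45 37.1, 53.0 and 114 ± 11.7 CPM. Of 44 G2M phase genes, 40 had positive changes (median 0.73), with 134, 241 and 332 ± 41.4 CPM of the mitotic kinase Cdk1 and 70.7, 123 and 203 ± 16.2 CPM of the proliferation marker Mki67 (each 0.127 adjusted over the list alone). Of 24 interferon response genes, 22 had negative changes (median −0.94), with 220, 160 and 44.1 ± 33.7 CPM of the GTPase Gbp2 and 93.5, 64.5 and 13.5 ± 6.92 CPM of Ifi44 (each 0.266 adjusted over the list alone). In the immediate early and stress list, whose median was −0.26 and whose mean was 0.75, the chaperone Hspa1a was higher adjusted over the list alone (0.00341), with 0.0318 CPM (1 count) at day 3 and 232 ± 125 at day 17. Without the table term the median of that list was 0.80, so no direction is given for it. The activity-induced factors Junb (522, 230 and 226 ± 63.3 CPM) and Egr1 (527, 194 and 220 ± 60.9 CPM) had p above the threshold with the list adjusted alone.

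**Figure D3:**
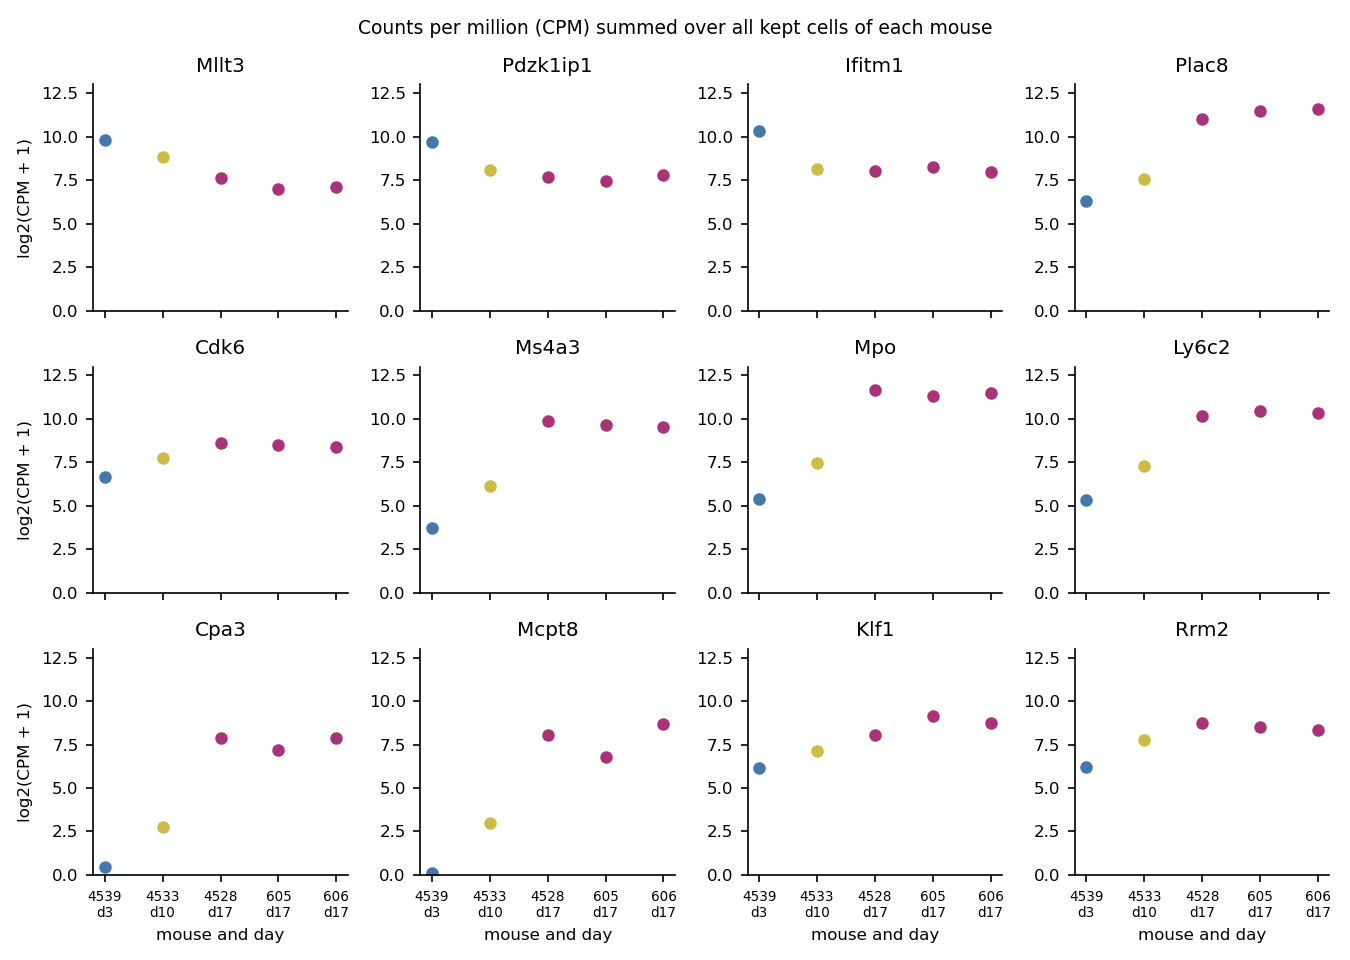
Level of 12 genes in the sum of all kept cells of each mouse, as log2 of TMM-scaled CPM plus 1, with 1 point per mouse and colour by day. Mllt3, Pdzk1ip1 and Ifitm1 lie highest in the day 3 mouse, and the other 9 genes, from Plac8 (78.5 CPM at day 3 and 2687 ± 516 at day 17) to Rrm2, lie highest in the 3 day 17 mice.

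Over all 16740 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes (lowest adjusted p = 0.106, Hdc), with 1473 genes at an unadjusted p under 0.05, of which 1072 were higher, against 837 expected by chance. DESeq2 called 455 (338 higher, 117 lower). Camera with the preset correlation called 15 of 21 lists, among them HSC (lower, adjusted p = 9.19e-14), neutrophil (2.69e-35), monocyte (1.23e-38), basophil or mast cell (4.19e-23), multipotent progenitor (8.26e-05), erythroid (0.00475), S phase (4.34e-26), G2M phase (1.61e-07) and interferon response (lower, 4.83e-05). With an estimated correlation no list was called, with adjusted p = 0.153 for HSC, neutrophil, monocyte, basophil or mast cell, S phase and interferon response, 0.170 for G2M phase, 0.244 for multipotent progenitor and 0.314 for erythroid, and the lowest adjusted p of fry was 0.0802. The preset test did not call the megakaryocyte (0.747), immediate early and stress (0.470), glycolysis (0.0900) or cholesterol synthesis (0.0887) lists. Ribosomal protein, mitochondrial respiration and mitochondrial genome genes had medians of −0.80, −0.39 and −0.48 with the table as a term but 1.40, 1.11 and 0.82 without it, so no direction is given for them (adjusted p = 0.449, 0.750 and 0.429 with an estimated correlation). Without mouse m4528, whose sex-linked genes differed, the first table holds days 3 and 10 only. With the table as a term, that mouse is the only day 17 mouse behind the slope. Day 17 and the difference in sex-linked genes therefore coincide in the slopes over all cells and over HSC-like cells, and cannot be told apart.

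The same test within HSC-like cells asked whether genes changed apart from the mix of classes. The neutrophil granule genes Mpo, Elane and Ctsg were higher when adjusted over the list alone, but erythroid-like cells of the day 17 mice held them at similar levels. Mpo had 7.46 CPM at day 3, 45.8 at day 10 and 398 ± 30.3 (SD, n = 3) at day 17, Elane, the neutrophil elastase, 1.94, 10.6 and 100.3 ± 20.5 CPM, and the protease Ctsg 1.84, 10.5 and 100.3 ± 33.6 CPM. In plain CPM, erythroid-like cells of mice m4528, m605 and m606 had 551, 270 and 357 of Mpo against 444, 332 and 382 in HSC-like cells, 103, 94.9 and 81.6 of Elane against 90.8, 104 and 92.6, and 140, 83.1 and 88.3 of Ctsg against 70.2, 113 and 102. Prtn3, a granule protease also listed for neutrophils and chosen after its values were seen, had 548, 484 and 506 ± 8.53 CPM in HSC-like cells. Of the lymphoid list, with 4 genes tested and so too few for a list test, the cytotoxic granule gene Nkg7 had 20.1, 31.9 and 125 ± 23.0 CPM (log2 change 2.92, SE 0.92). In plain CPM it had 157, 91.4 and 119 in HSC-like cells of mice m4528, m605 and m606, 53.5, 48.0 and 36.3 in erythroid-like cells and 3358, 3987 and 4263 in neutrophil-like cells. At most 12.9% of the HSC-like cells held over 10 counts, and counts from other cells of the plates were not excluded. Il7r, the receptor of interleukin 7, had no counts at days 3 and 10 and 16.1, 3.61 and 0 CPM in mice m4528, m605 and m606, at least 46.4-fold higher at day 17 than a floor of 3 counts in the day 3 mouse. It was found in 3.64% of 55 and 12.5% of 16 cells of mice m4528 and m605. Of the 55 cells of mouse m4528, 1.82% held over 10 counts. In plain CPM that mouse had 16.7 of Il7r in HSC-like cells and 23.1 in megakaryocyte-like cells. HSC list genes split into 7 with positive and 8 with negative changes (median −0.03). HSC-like clusters were named from these same genes, which were not kept out of clustering. The split was therefore in part set by the choice of cells and does not show that the genes held steady. The progenitor gene Plac8 had 28.4, 49.0 and 406 ± 251 CPM, with 129, 409 and 626 plain CPM in HSC-like and 239, 207 and 210 in erythroid-like cells of mice m4528, m605 and m606. Btg2, an antiproliferative immediate early gene, had 134 and 45.1 CPM at days 3 and 10 against 19.6, 627 and 510 CPM in mice m4528, m605 and m606, with a fitted change of −2.78 that became 1.81 without the table term.

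Over 12271 genes, edgeR's quasi-likelihood test called 0 (lowest adjusted p = 1), with 266 genes at an unadjusted p under 0.05 against 614 expected by chance, and DESeq2 called 5, with Mpo, Elane and Ctsg higher and Mlf1 and Morn2 lower (the last pair chosen after their values were seen). Adjusted over the list alone, Mpo (0.000814), Elane (0.00788), Ctsg (0.00788), Nkg7 and Il7r (0.0372 each) passed, and of the 6 neutrophil genes tested 5 had positive changes. Camera with the preset correlation called the neutrophil (9.06e-19), monocyte (0.0135) and multipotent progenitor (0.00644) lists as higher, the G2M phase list (7.57e-08) as lower, and the ribosomal protein (3.57e-05) and mitochondrial respiration (1.21e-07) lists, and none with an estimated correlation (adjusted p = 0.602 for each except ribosomal protein, 0.726). The medians of the ribosomal protein and mitochondrial respiration lists were −0.79 and −0.97 with the table as a term but 1.25 and 0.45 without it, so no direction is given for them. The G2M phase gene Ube2c had 60.7 and 10.7 CPM at days 3 and 10 and 1.63, 9.63 and 78.3 CPM in the day 17 mice. HSC-like cells of days 3 and 10 lay mostly in cluster 3, and those of mouse m606 mostly in cluster 5 (22 of 31 cells), which is led by immediate early genes, and the simulated recovery of 4-fold changes in this fit was 1%.

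The last comparison asked how genes kept out of clustering differed between classes of the same mice, first megakaryocyte-like against HSC-like cells in 5 mice. Megakaryocyte-like cells had higher levels of cell cycle genes and lower levels of interferon response genes. Mki67 was higher at 188 ± 29.4 CPM against 32.0 ± 8.77 (log2 change 2.59, SE 0.27, edgeR adjusted p = 0.0164, higher in 5 of 5 mice). The mitotic genes Ccnb1, Ccnb2, Birc5 and Hmmr rose too, by 2.26 to 3.14, with 362 ± 177 CPM of the cyclin Ccnb2 against 62.9 ± 36.8. In the S phase list Mcm5 (270 ± 105 against 74.2 ± 18.3 CPM), Mcm6, Tipin and Gmnn, a brake on repeated replication, rose by 1.32 to 1.81. The lactate dehydrogenase Ldha rose by 1.12 on the log2 scale (868 ± 128 against 403 ± 90.3 CPM), and 8 of 88 mitochondrial respiration genes rose, among them the oxidase subunit Cox5a (772 ± 481 against 319 ± 166 CPM), Ndufb7 and Ndufb9. Of 20 immediate early and stress genes, 4 fell and 1 rose. Egr1 fell to 257 ± 141 from 921 ± 556 CPM (log2 change −1.82, SE 0.11, adjusted p = 0.00379) and Junb to 153 ± 56.6 from 745 ± 401 CPM, with Klf6 and Zfp36 also lower and Hspa1a higher (in 4 of 5 mice). The interferon response genes Ifi44 (18.3 ± 7.97 against 109 ± 53.0 CPM) and Iigp1 fell, as did Mt-Rnr2 and Rps9.

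Of 79 cell cycle genes, 9 passed over all genes, all higher, and 47 adjusted over the list alone (18 of 35 S phase and 30 of 44 G2M phase genes in their own lists). The median of the 79 changes was 1.73 (SD over genes 0.934). By camera with an estimated correlation the adjusted p was 0.0306 for S phase, G2M phase and interferon response and 0.0131 for mitochondrial respiration. It was 0.144 for the immediate early and stress list, whose preset call (0.000208) was lost in that version. By fry the adjusted p was 0.00290, 0.00313, 0.00313 and 0.000722 for S phase, G2M phase, interferon response and mitochondrial respiration. For the immediate early and stress list fry gave 0.0264. The mitochondrial genome list (preset 0.0376) had an adjusted p of 0.432 with an estimated correlation, and ribosomal protein (0.468), glycolysis (0.631) and cholesterol synthesis (0.468) lists were not called by the preset test. The count of 9 cell cycle genes became 0 to 4 with any of the 5 mice left out, and 0 without the HSC-like cluster led by immediate early genes. That left 3 mice, and no list was called with an estimated correlation (adjusted p = 0.212 for S phase, G2M phase and mitochondrial respiration, and 0.206 for interferon response). Adjusted over the list alone, 12 S phase, 16 G2M phase and 0 respiration genes were then higher, against 18, 30 and 29 with the cluster, and the list medians were 1.62, 2.22 and 0.51 against 1.37, 2.06 and 0.57.

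Erythroid-like cells, compared in the 3 day 17 mice, had higher levels of 27 of 79 cell cycle genes than HSC-like cells. The list tests differed, since camera with an estimated correlation called no list while fry called several. The centromere histone Cenpa was 1174 ± 160 CPM against 161 ± 43.7 (log2 change 2.89, SE 0.22, edgeR adjusted p = 0.00950, 3 of 3 mice). Cdca8, of the chromosome passenger complex, rose to 480 ± 71.4 from 93.9 ± 25.7 CPM, and Gmnn to 574 ± 75.8 from 96.9 ± 23.2, and Rrm1, the large subunit of the deoxynucleotide-making enzyme, to 747 ± 276 from 125 ± 38.9. Of 87 mitochondrial respiration genes 13 rose, such as Cox6a1 (981 ± 541 against 293 ± 176 CPM), and Cox4i2 fell, while the mitochondrially encoded Mt-Nd1 rose to 4676 ± 386 from 2548 ± 134 CPM. Of 20 immediate early and stress genes 9 fell, among them Zfp36, which speeds decay of cytokine transcripts (56.7 ± 27.4 against 2616 ± 1677 CPM), and the phosphatase Dusp1 (251 ± 145 against 3148 ± 1349 CPM). The interferon response genes Gbp2 (1.34 ± 0.735 against 146 ± 121 CPM), Iigp1 and Ifi47 fell, and the glycolytic enzyme Pkm fell to 18.1 ± 20.4 from 170 ± 79.2 CPM. Of the HSC-like cells, 7 of 16 in mouse m605 and 22 of 31 in mouse m606 lay in the cluster led by immediate early genes.

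**Figure D4:**
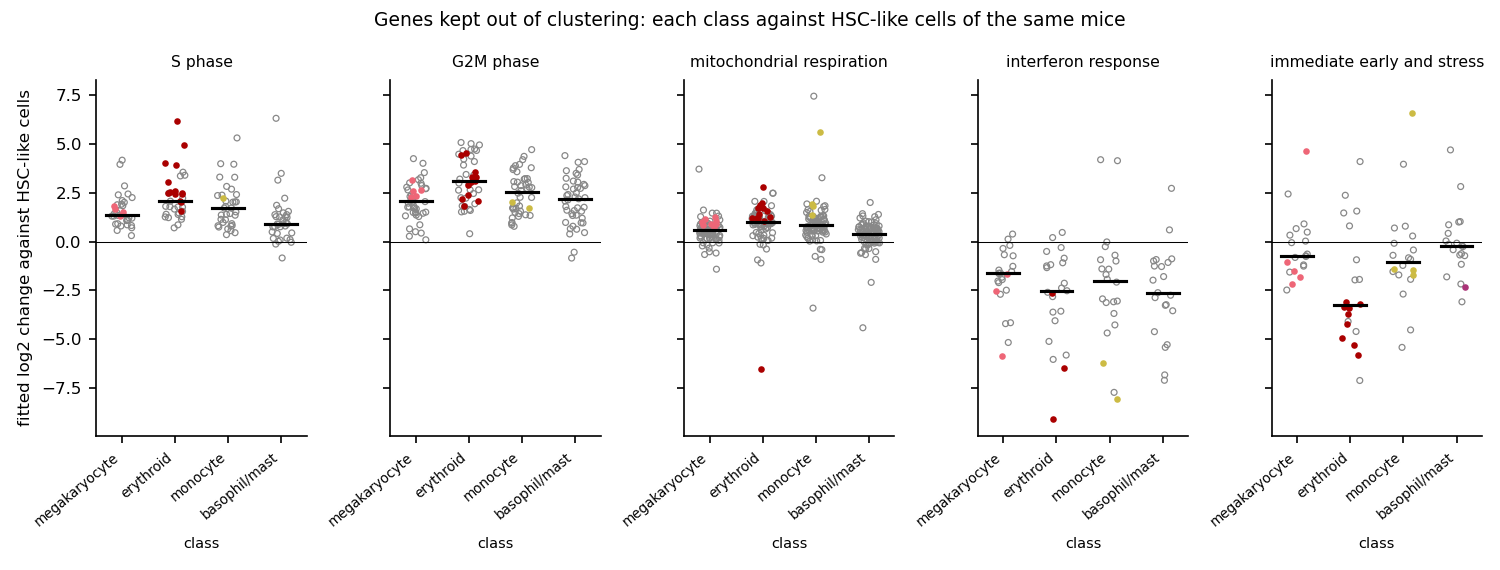
Fitted log2 change against HSC-like cells of the same mice (vertical axis) for the genes of 5 lists kept out of clustering, with 1 point per gene, the classes along the horizontal axis, filled points for genes past the adjusted threshold over all genes and a black bar at each median. S phase and G2M phase medians lie above 0 in the 4 classes, and interferon response medians lie below 0.

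Of 79 cell cycle genes 27 passed over all genes, all higher, and 66 adjusted over the list alone, with a median change of 2.51. Camera's preset calls for S phase, G2M phase, mitochondrial respiration and interferon response were lost with an estimated correlation (adjusted p = 0.164 each), as was that for immediate early and stress genes (0.301). By fry the adjusted p was 0.0226 for each of the former lists and 0.0495 for immediate early and stress genes. Ribosomal protein (0.398), mitochondrial genome (0.282), glycolysis (0.337) and cholesterol synthesis (0.803) lists were not called by the preset test. The count became 1 without mouse m4528, 11 without mouse m605 and 10 without mouse m606. Only 11 erythroid-like cells of mouse m4528 were in its sum.

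Monocyte-like cells of the 3 day 17 mice had higher levels of 3 of 79 cell cycle genes than HSC-like cells. Gmnn rose to 468 ± 233 from 95.2 ± 22.5 CPM (log2 change 2.21, SE 0.32, edgeR adjusted p = 0.0429, 3 of 3 mice), the condensin subunit Smc4 to 502 ± 47.5 from 157 ± 38.8 and Cdca8 to 367 ± 32.0 from 92.1 ± 24.9. Of the respiration genes Cox5a (1399 ± 911 against 362 ± 187 CPM), Cox6a1, Cox6a2 and Uqcrq rose. Cox6a2, which is also on the dendritic cell marker list, had 151 ± 229 CPM against 3.10 ± 4.88. Its level was uneven between mice, with 3.09, 84.0 and 8.14 CPM in all kept cells of mice m4528, m605 and m606. Hspa1a, a heat shock chaperone whose reads may be shared with its copy, rose to 511 ± 264 from 7.92 ± 7.92 CPM, while Dusp1 fell to 1032 ± 696 from 3094 ± 1326 CPM along with Ier2 and Jun. The interferon response genes Rtp4 (2.58 ± 2.44 against 153 ± 37.3 CPM) and Ifi44 (0.287 ± 0.249 against 78.8 ± 46.0 CPM) fell, as did Mt-Rnr2 and Rps14.

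Of 79 cell cycle genes 3 passed over all genes and 42 adjusted over the list alone (median change 2.03). Camera's preset calls for S phase, G2M phase, mitochondrial respiration, interferon response and immediate early and stress genes were lost with an estimated correlation (adjusted p = 0.182, 0.283, 0.115, 0.201 and 0.631). By fry the adjusted p was 0.0433, 0.0576, 0.0224, 0.0499 and 0.163 in the same order of lists. The ribosomal protein (0.986), mitochondrial genome (0.645), glycolysis (0.591) and cholesterol synthesis (0.986) lists were not called by the preset test. Without mouse m4528 or mouse m606 the count of cell cycle genes was 0, and with no mouse block it was 18.

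In basophil or mast cell-like cells of the 3 day 17 mice the replication regulator E2f8 had 113 ± 53.8 CPM against 1.22 ± 0.453 in HSC-like cells (log2 change 6.33, SE 0.87, edgeR adjusted p = 0.127 over all genes and 0.0181 adjusted over the list alone). The cluster behind this class also had multipotent progenitor and erythroid markers raised. Mice m605 and m606 gave 16 and 26 cells to the contrast, while separate clustering of their table gave this name to 9 cells. Zfp36 fell to 501 ± 313 from 2668 ± 1751 CPM (log2 change −2.35, SE 0.20, adjusted p = 0.0428). EdgeR's quasi-likelihood test called 0 of 79 cell cycle genes over all genes, with 27 at an unadjusted p under 0.05, while DESeq2 called 20, and the median change was 1.38. Camera's preset calls for S phase, G2M phase, mitochondrial respiration and interferon response were lost with an estimated correlation (adjusted p = 0.114, 0.234, 0.114 and 0.114). By fry the adjusted p was 0.0411, 0.0967, 0.0411 and 0.0411 in the same order of lists. Immediate early and stress (0.224), ribosomal protein (0.248), mitochondrial genome (0.850), glycolysis (0.597) and cholesterol synthesis (0.304) lists were not called by the preset test. Whether the contrasts differed between the classes was not tested. Neutrophil-like cells reached the minimum of 10 cells in mouse m4528 only and were not compared.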

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

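The tests in this part were chosen after the values had been seen. Mouse m4528 held transcripts of the Y chromosome, which stood out because the other mice had almost none. Eif2s3y, a translation factor subunit, had 131 CPM in mouse m4528 and at most 0.20 in the other 4 mice, and the RNA helicase Ddx3y had 55.3 CPM against at most 0.235. In the same mouse Xist, the transcript of the inactive X chromosome, had 0.156 CPM, against 454 in mouse m4539, 181 in mouse m4533, 918 in mouse m605 and 1242 in mouse m606. The labels used here give no sex for single mice, and sex of the animal was not separated from the other differences between mice.

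The plate of mice m605 and m606 together, whose cells carry no single mouse name and entered no mouse sum of the main comparisons, held monocyte-like cells at 17.2% of 93 cells (exact 95% interval 10.2 to 26.4). This was above the 3.23% that 3 cells would make, a limit that any class with more than 3 cells passes. It lay inside the range of the 3 named day 17 mice (15.97% to 20.28%), so the plate did not stand out. Over the day 17 plates, 13 measures were searched for a plate far from the others, and 0 passed Dixon's 95% critical value.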

How the results depend on the processing

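Alternatives added after seeing the data were at least 500 genes alone, a mean of at least 10 CPM, leaving out 147 highest-count cells on the scale of counts, and leaving out the HSC-like cluster led by immediate early genes. Of 314 comparisons of a count or share with an alternative, 232 kept within the spread or within 1.5 times the count and 82 moved, and the cause was not tested unless stated. The day slope in all cells called 0 genes, and 455 with DESeq2, 18 with no table term, 13 with day as a factor, 52 with thinned cells, 6 with the mixed plate as a unit and 106 at a mean of at least 10 CPM, where fewer genes are tested, and 0 to 0 with a mouse left out. In HSC-like cells the count of 0 became 5 with DESeq2, 4 with no low-count filter (Mpo, Trbc1, Mapt and Xist), 1 with day as a factor (Xist), 1 with thinned cells (Mpo) and 0 to 1 with a mouse left out (Xist without mouse m4533, Fosb without mouse m4528). The calls of Xist cannot be read as a change with day. Mouse m4528, the only day 17 mouse of the first table, is the mouse whose sex-linked genes differed. Cell cycle genes in megakaryocyte-like cells (9) became 14 with no filter, 16 at 10 CPM, 55 with DESeq2, 14 with no mouse block, 32 with thinned cells, 0 without the cluster led by immediate early genes, where 3 mice were left, and 0 to 4 with a mouse left out (0 without mouse m4539, m4533 or m4528, 1 without mouse m606, Tipin, and 4 without mouse m605, Mki67, Cdca8, Dut and Tacc3). Without that cluster the list medians were 1.62 for S phase and 2.22 for G2M phase (1.37 and 2.06 with it), and the list calls with an estimated correlation were lost, from an adjusted p of 0.0306 to 0.212 for S phase and G2M phase and to 0.206 for interferon response, and from 0.0131 to 0.212 for mitochondrial respiration. By fry the adjusted p was 0.0604, 0.0902 and 0.0604 for S phase, G2M phase and mitochondrial respiration and 0.0305 for interferon response. In erythroid-like cells the 27 became 46, 43, 69 and 58 with no filter, 10 CPM, DESeq2 and thinned cells, and 1 (Cenpa, without mouse m4528) to 11 with a mouse left out. In monocyte-like cells the 3 became 22, 18, 51, 18 and 35 with no filter, 10 CPM, DESeq2, no mouse block and thinned cells, and 0 to 4 with a mouse left out (0 without mouse m4528 or m606, and Ccnb2, Cdca8, Fen1 and Rrm2 without mouse m605). In basophil or mast cell-like cells the 0 became 20 with DESeq2, 1 with no mouse block (E2f8) and 2 with thinned cells (Cdca3 and Top2a). Lists called with the preset correlation (15 and 6) became 0 and 0 with an estimated correlation. The HSC-like share of cells at day 3 (81.6%) was 93.2% at resolution 0.5, 75.3% at resolution 2 and with separate clustering, 67.9% by marker score and 87.1% at 500 genes alone, and 78.1% to 85.1% with a plate left out. The HSC-like share of cells at day 10 (52.3%) was 68.2% at resolution 0.5, 29.0% by marker score and 30.3% at 500 genes alone, and the HSC-like share of cells at day 17 (15.6%) was 26.9% and 8.70% at resolutions 0.5 and 2, 11.1% by marker score and 10.3% without the cluster led by immediate early genes. The fall from day 3 over day 10 to day 17 held in 10 of 10 settings. With the highest-count cells left out on the scale of counts, the HSC-like share of cells at day 10 was 69.1%, the megakaryocyte-like share of cells at day 10 was 10.3%, the neutrophil-like share of cells at day 17 was 3.76%, and the erythroid-like share of cells at day 3 and the erythroid-like, neutrophil-like and monocyte-like shares at day 10 were 0. By marker score the megakaryocyte-like share of cells at day 3 was 3.68%, the megakaryocyte-like share of cells at day 10 was 17.8% and the megakaryocyte-like share of cells at day 17 was 13.3%, with 3.50% and 14.3% at days 10 and 17 at 500 genes alone. With a day 10 plate left out, erythroid-like cells were 0% to 4.69%, neutrophil-like cells 0% to 1.56% and monocyte-like cells 0% to 4.05%. The neutrophil-like share of cells at day 17 (5.42%) was 11.2% at resolution 0.5, 8.99% with separate clustering, 8.28% by marker score and 14.8% at 500 genes alone. The monocyte-like share of cells at day 17 (18.1%) was 10.7% at resolution 2, 14.4% with separate clustering, 6.83% by marker score and 11.1% at 500 genes alone. The basophil or mast cell-like share of cells at day 17 (10.5%) was 0% and 2.68% at resolutions 0.5 and 2, 1.58% with separate clustering, 2.98% by marker score and 1.82% at 500 genes alone. Of 1270 comparisons of a single gene with an alternative, 951 kept direction and side of the threshold, 213 lost and 98 gained the threshold, and 8 reversed, in 7 results. Without mouse m4528 the fitted change was 0 for Dntt, Prg3, Ly6d and Bglap, since the remaining mice of the first table had no counts, and −6.53 for Siglech, while the highest values with a mouse left out were 26.88, 26.61, 23.08, 17.22 and 23.87. Btg2 in HSC-like cells had 1.81 with no table term, and Prtn3 had −0.30 to 0.17 with a mouse left out (0.17 without mouse m4539) and 0.13 at 500 genes alone. The contrasts of erythroid-like, monocyte-like and basophil or mast cell-like cells without the cluster led by immediate early genes were not run, because too few mice had 10 cells. With 1 mouse at day 3 and 1 at day 10, simulated 4-fold changes were recovered at 16% in all cells and at 1% in HSC-like cells.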

Other observations

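A few genes from lists of lineages without a named class, such as Dntt, Rag2, Nkg7 and Ly6d, rose with day adjusted over their list alone. Being on such a list does not place a gene outside the named classes. Nkg7 had 3358, 3987 and 4263 plain CPM in neutrophil-like cells of mice m4528, m605 and m606. That was above its levels in HSC-like, megakaryocyte-like, erythroid-like and monocyte-like cells. The tests in this part were chosen after the values had been seen, apart from the list tests and both tests of immediate early genes. Dntt, the polymerase that adds bases at antigen receptor joins, had no counts at days 3 and 10 and 34.7, 10.5 and 5.46 CPM in mice m4528, m605 and m606, at least 177-fold higher at day 17 than a floor of 3 counts in the day 3 mouse. Rag2, of the enzyme that cuts antigen receptor genes, had 3.21, 0.979 and 0.871 CPM in mice m4528, m605 and m606, at least 17.7-fold higher by the same floor. Nkg7, a granule membrane gene of cytotoxic cells, had 73.0, 157 and 971 ± 176 CPM (SD, n = 3). By edgeR's quasi-likelihood test each had 0.00423 adjusted over the list alone, and Ly6d, a marker of early B-lineage cells, had 0.0175 with 9.32, 135 and 17.5 CPM in the day 17 mice. Ly6d lay outside the rule and was chosen afterwards. The lymphoid list was called as higher by camera with the preset correlation (adjusted p = 4.47e-07) but not with an estimated correlation (adjusted p = 0.314). The eosinophil granule genes Prg2 and Prg3 had 181 and 31.6 CPM in mouse m4528 and at most 2.91 and 5.12 in mice m605 and m606 (list adjusted p = 2.27e-09 preset, 0.153 with an estimated correlation). Siglecf, of the same list, had 27.1, 13.1 and 12.6 CPM in mice m4528, m605 and m606. It had 0.0635 (2 counts) and 5.10 CPM at days 3 and 10 (0.00953 adjusted over the list alone by edgeR's quasi-likelihood test). By the marker rule used for naming, Prg2 was raised in the basophil or mast cell-like cluster 10 only, and Dntt in unnamed cluster 9 only. Without mouse m4528 the fitted changes of Dntt, Prg3 and Ly6d were 0.

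Siglech, a marker of plasmacytoid dendritic cells, had 0.0318 CPM (1 count) at day 3 and 18.8 ± 7.72 at day 17, and the class II gene H2-Ab1 had 76.1, 107 and 122 ± 75.0 CPM (each 0.0682 adjusted over the list alone; dendritic cell list 0.0285 preset, adjusted p = 0.277 with an estimated correlation), and without mouse m4528 the fitted change of Siglech was −6.53. The median change of the dendritic cell list was 1.97 with the table as a term but −0.26 without it, so no direction is given for that list. Adgre1, which encodes the macrophage antigen F4/80, had 11.1, 0.890 and 1.54 CPM in mice m4528, m605 and m606 against no counts at day 3 (macrophage list adjusted p = 0.0707 preset). Of the same list, Slc40a1 had 3.94, 9.72 and 32.9 ± 8.80 CPM (0.0235 adjusted over the list alone by edgeR's quasi-likelihood test). C1qa was under 1 CPM in every mouse, with no counts at day 17. The bone matrix genes Sparc, Col1a2 and Bglap had 112, 121 and 137 CPM in mouse m605 and at most 11.4 in mice m4528 and m606 (stromal or endothelial list adjusted p = 0.219 preset). Bglap lay outside the rule and was chosen afterwards. Cdh5, which the rule named, had 0.350, 0.0237 and 0.390 ± 0.535 CPM (log2 change −3.55). The mature B or plasma cell list had too few tested genes for a list test, and of its members the immunoglobulin heavy chain gene Ighm had 13.2, 73.6 and 269 ± 85.1 CPM (0.000155 adjusted over the list alone), while Fcrla was under 1 CPM in every mouse (log2 change −8.38, 0.0227). By the marker rule used for naming, Ighm was raised in the monocyte-like clusters 6 and 7 only. Siglech was raised in cluster 7 only and Adgre1 in cluster 6 only, so the clusters in which these 3 genes were raised had the monocyte name. Cluster 7 also had the dendritic cell markers H2-Ab1 and Cox6a2 raised. The rule looks at whole clusters and cannot tell which of their cells held a gene, so dendritic cells within cluster 7 are not excluded. On the plate of mice m605 and m606 together, HSC-like cells were 18.3% of 93, megakaryocyte-like 21.5%, erythroid-like 18.3%, neutrophil-like 6.45% and basophil or mast cell-like 11.8%, while unnamed cluster 9 was 6.45% and cluster 2 was 0 of 93, which allows up to 3.23%.

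Mpo in HSC-like cells of day 17 mice may come from other cells of the same plates. The median Mpo count per erythroid-like cell was at least 3.38 times that per HSC-like cell in the 3 mice, in which erythroid-like cells held more counts, and Mpo counts were found in every HSC-like cell of those mice but in 47.1% at day 3. Barcodes below the filters had 12317, 4528.4 and 7233 CPM of Mpo in mice m4528, m605 and m606 against 351 at day 3, above the 3242, 2284 and 2850 in kept cells, and 48.4%, 34.0% and 34.3% of them held Mpo. Expression above the level of erythroid-like cells was argued against, since the ratio of Mpo CPM was at most 1.23, while Prtn3 reached at least 5.57 in the same comparison. A level of its own in HSC-like cells stays open. For each neutrophil gene, the CPM in HSC-like cells was taken as a share of the CPM in all cells. The share of Mpo was at least 1.76 times the median share, which met the first rule set for it. Erythroid-like cells showed the same excess of that share (at least 2.03), a requirement added after the first value was seen.

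Immediate early genes were higher in HSC-like cells of mice m605 and m606 than of mouse m4528 (median log2 ratio 2.13 over 21 genes). Handling or library batch could account for it and cannot be told apart from a difference between mice, since the ratio was 1.30, 1.11 and 0.709 in megakaryocyte-like, monocyte-like and erythroid-like cells, above 0 in each but under the level set for a batch effect in erythroid-like cells, and 1.85 in basophil or mast cell-like cells, which the rule did not name. Fewer counts per cell stay open too. The cluster led by immediate early genes had 1.04 times the median counts of the other HSC-like cells in mice m605 and m606, but that rule was set within mice while the pattern lies between mice, and HSC-like cells of these mice had medians of 51342.5 and 62562 counts against 90972 in mouse m4528, a comparison added after the ratio was seen. No biological explanation was tested.

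Erythroid-like cells were 3.82% in mouse m4528 against 25.9% and 16.9% in mice m605 and m606. Clustering both tables together was argued against as the only source, since separate clustering still gave 7.64% against 23.1% and 15.9%. The gap was smaller than with joint clustering, so a part of it may come from clustering the tables together. A single plate was argued against too, because the highest plate of mouse m4528 had 5.88% and the lowest plate of mice m605 and m606 had 12.6%. The table, the sort gate and the sex of the animal stay open and untested.

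For the 9 cell cycle genes of megakaryocyte-like against HSC-like cells, 1 of 16 splits that exchange the 2 sums within mice, the real one, gave as many, and the highest of the others was 0. The same count was 1 of 4 for erythroid-like cells (27 genes) and monocyte-like cells (3 genes), with a highest other of 0. For basophil or mast cell-like cells the real count and the highest other were 0, so the 4 of 4 splits that gave as many were fixed beforehand and say nothing. With 16 or 4 splits these designs are too small for a share under 0.05. With splits that may place both sums of a mouse on the same side there were 126 and 10, and of 100 of the 126 drawn only the real one gave 9, but such splits do not keep the pairs, and the count within mice replaced this one after its value was seen.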
